A study of Homo sapiens with 12 samples.

How the data were processed

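HEK293T cells, an established human embryonic kidney cell line, were treated for 3 h with DMSO (the solvent control), with i14G1-10 at 20 µM or with i14G1-12 at 10 µM. The series title describes both compounds as inhibitors of the contact between the initiation factors eIF1 and eIF4G1. Each treatment was profiled by Ribo-seq, which sequences the mRNA stretches protected by ribosomes held with cycloheximide, and by TI-seq, in which harringtonine collects ribosomes at start codons before cycloheximide is added. There were 2 libraries per treatment and assay, 12 in all. The labels do not say whether the 2 libraries of a treatment came from separate cultures. P-values for single genes or for shares therefore measure only the spread between libraries. Those for gene lists are described below.

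The deposited table gives a normalised signal for the 5′ UTR and for the coding sequence of 7417 genes in each library, in 24 columns of values, all of which were used. Per the submitters' processing notes, cutadapt, Bowtie, TopHat2, HTSeq, DESeq2 and the build hg38 were used, with versions not given in the sources used here. Every value was a whole multiple of its library's smallest value (100% of values, to within 4.54e-05 of a whole number or less), and the step was shared by the 5′ UTR and coding columns of a library. The values are therefore read counts divided by 1 factor per library, and whole reads were recovered by dividing by that step. A single read was worth between 0.34 and 2.55 normalised units. No value was 0, and the smallest was worth 1 read in every library; whether zeros were set to 1 or 1 was added to all counts could not be settled from the table. Every gene had at least 50 reads over both regions in at least 1 library, so genes with few reads everywhere are missing from the deposited table. One TI-seq column has an irregular replicate number in its header; it was assigned to the second i14G1-10 library because every other library had its pair of columns. How reads at the start codon itself were divided between the 5′ UTR and the coding sequence is not given in the sources used here. No mRNA measurement was used here, so a change in footprints combines a change in mRNA level and a change in translation.

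The main measure was the coding signal. The plan made before the data were examined had assumed 1 value per gene; the table gives both regions, and the coding sequence was taken in its place. The 5′ UTR signal, the ratio of 5′ UTR to coding signal and the 5′ UTR share of a library's reads were added after the table had been seen. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1) with a mean-variance trend, in 1 fit to the 6 libraries of an assay, over genes with a mean of at least 10 normalised reads. The ratio was fitted as the difference of both log2 values. Adjusted p-values are Benjamini-Hochberg values, and genes under 0.05 are described as changed. Estimates are given on the log2 scale with their standard error. The 5′ UTR share of a library left out cells at the 1 read minimum and was compared between treatments by an exact two-sided permutation test; with 2 libraries against 2 there are 6 splits, and the smallest p possible is 0.333. Its 95% intervals are exact (Clopper-Pearson) binomial intervals. Reads were amplified by PCR and no molecular identifiers are described, so these intervals cover counting error only. Where a group was at the minimum in both libraries, the fold was also computed with that group set to 3 reads over the group. Such a fold takes the other group's mean as it is and leaves out its counting error, so it is no strict lower bound.

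Gene lists were written before the data were examined and tested with camera (preset correlation 0.01), which asks whether a list's genes moved more than the other genes, adjusted over the 19 lists with at least 5 tested members. The same test with a correlation estimated from the libraries, and fry, which asks whether a list's genes moved on balance one way, were run beside it. At the preset correlation, camera's p rests on the spread across genes under an assumed correlation, not on the spread between libraries alone. Of 24 cytokine and NF-κB genes, 4 were in the table and were not tested as a list. Lists of mitochondrially encoded genes, snoRNA hosts, abundant noncoding RNAs and markers of fibroblasts, blood cells and keratinocytes had 0 members in the table. Symbols were matched to RefSeq on GRCh38.p14: 7148 were current, 258 matched 1 older name and 11 were ambiguous. Gene positions come from that annotation. HSPA1A and HSPA1B are nearly identical, as are many histone genes, so reads may have been assigned to either copy.

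Named genes followed a rule set before the data were examined. Among genes with an adjusted p under 0.05, a mean of at least 50 over the 6 libraries and both treated libraries on the same side of both control libraries, the 10 largest rises and the 10 largest falls were taken for each compound against DMSO, and 5 each way between the compounds. EIF1, EIF4G1, EIF5, ATF4, DDIT3, PPP1R15A, HSPA5 and XBP1 were always named, with up to 4 members of each described list. Genes outside the rule are named only where stated.

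Alternatives were other pseudocounts, no filter or a stricter one, rescaling to equal totals, quantile normalisation, limma without trend, fits to only the 4 libraries compared, a replicate block, edgeR 4.0.16 with TMM and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Subtracting 1 read, thinning all libraries to the shallowest one and the edgeR interaction of region and treatment were added after the data were seen. The scaling of the deposited values was kept in the main fits. Similarity of the compounds was compared with 100 simulations in which both compounds had no effect but shared the same controls. The tests were tested on simulated data with the depth of each library. Each gene's mean and spread were taken over all 6 libraries of an assay, not from 1 comparison. Changes were placed in i14G1-12 and tested against DMSO. There, limma recovered 25.4% of coding changes of 1.5-fold, 66.7% of 2-fold and 98.4% of 4-fold changes in Ribo-seq, with 2 false calls among 7205 genes. For TI-seq it recovered 5.97%, 21.5% and 84.6%, and for the Ribo-seq ratio 0%, 5% and 68.9%. It made 0 calls when nothing had been changed, as did edgeR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.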

Results

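The study's title asks about translation of stress-response genes and of 5′ UTRs under inhibitors of the eIF1-eIF4G1 contact. Ribosome footprints of HEK293T cells were compared after 3 h of DMSO, i14G1-10 (20 µM) or i14G1-12 (10 µM), with 2 Ribo-seq and 2 TI-seq libraries per treatment. The table held between 653768 and 3614548 reads per Ribo-seq library and between 459535 and 1644634 per TI-seq library. Both DMSO Ribo-seq libraries were deeper (3026393 and 3614548 reads) than the treated ones, and the shallowest was the second i14G1-10 library. Coding signals of the 2 libraries of a treatment correlated across genes with r = 0.986 (DMSO), 0.967 (i14G1-10) and 0.980 (i14G1-12) in Ribo-seq, and with 0.957, 0.944 and 0.918 in TI-seq. Genes are not independent replicates. All values below are normalised reads per gene as mean ± SD over 2 libraries, or limma estimates on the log2 scale.

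With i14G1-10, footprints rose on genes of the integrated stress response, heat shock and oxidative stress. CHAC1, an enzyme that breaks down glutathione, went from 12.6 ± 0.508 coding reads in DMSO to 145 ± 15.2 (log2 change 3.43, SE 0.18, n = 2 and 2, adjusted p = 2.94e-10 by limma). The stress-induced transcription factor ATF3 rose by 3.31 and HMOX1, which degrades heme, by 2.89. Inducible Hsp70 (HSPA1B, nearly identical to HSPA1A) rose from 157 ± 12.4 to 1070 ± 105, and PPP1R15A, the stress-induced subunit that directs phosphatase to eIF2α, from 4.23 ± 1.23 to 26.2 ± 6.53 (adjusted p = 1.62e-05). Among the falls were PABPC1, the cytoplasmic poly(A)-binding protein, from 549 ± 19.1 to 239 ± 7.66 (log2 change −1.19, SE 0.121, adjusted p = 3.25e-06), and SRM, which makes spermidine, from 244 ± 1.91 to 112 ± 2.09.

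In all, 218 coding sequences rose and 155 fell of 7224 tested with i14G1-10 against DMSO, 65 and 77 of them by at least 2-fold. Other large rises were those of STC2 (2.26), ISL2 (1.91), the cystine transporter SLC7A11 (1.83) and the myosin MYO6 (1.79). Falls also included CLPTM1L (−1.23) and PRELID1 (−1.18), and with calls that 1 or more alternatives ended, EI24 (−1.91), TMEM147 (−1.29), RHOB (−1.28), PPP1R14B (−1.19), JTB (−1.19) and CHPT1 (−1.08). ATF4, the main transcription factor of the integrated stress response, rose from 174 ± 3.39 to 392 ± 186 (log2 change 1.08, SE 0.204, adjusted p = 0.00405), with 260 and 523 in the 2 treated libraries. The call ended without the variance trend and in DESeq2. XBP1, a transcription factor of the unfolded protein response, rose by 1.63 (adjusted p = 3.65e-07). The proposed target genes did not pass: EIF1 had a log2 change of 0.38 (adjusted p = 0.0572) and EIF4G1 of −0.03 (0.916), and EIF5, which acts in start codon choice, had −0.07 (0.781). HSPA5, the ER chaperone BiP, had 0.26 (0.191) and DDIT3, encoding CHOP, 2.12 (0.063) on 11 against 5 reads. HSPA6, an inducible Hsp70, passed on 9 against 5 reads (log2 change 1.95, adjusted p = 0.00692), a call that 9 alternatives ended.

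On GRCh38.p14, CHAC1 lies on chromosome 15 (40953471 to 40956512), ATF4 on chromosome 22 (39520559 to 39522686), XBP1 on chromosome 22 (28794560 to 28800569) and PPP1R15A on chromosome 19 (48872421 to 48876058). EIF1 lies on chromosome 17 (41688885 to 41692668), EIF4G1 on chromosome 3 (184314606 to 184335358) and EIF5 on chromosome 14 (103334237 to 103345025). DDIT3 is on chromosome 12 (57516588 to 57520517), HSPA5 on chromosome 9 (125234853 to 125241343) and HSPA6 on chromosome 1 (161524540 to 161526894). All are annotated as protein-coding, and the values are sums over their annotated 5′ UTR or coding sequence.

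The ATF4 list holds genes of ATF4 and the integrated stress response, ATF4 itself among them. Of its 40 tested genes, 27 rose and 0 fell with i14G1-10 (34 and 0 adjusted over the list alone), with a median log2 change of 0.92. Besides CHAC1 and ATF3 they included SLC3A2, a subunit of amino acid transporters (1.49). The list stood above the other genes by camera (adjusted p = 1.04e-39, adjusted p = 0.102 with an estimated correlation). Of 30 heat shock genes 12 rose and 0 fell (15 and 0 adjusted over the list alone). The Hsp40 DNAJB1 (1.70) and the co-chaperone BAG3 (1.34) were among them, and the list's adjusted p was 3.69e-13 (adjusted p = 0.141 with an estimated correlation). Of 22 NRF2 and oxidative stress genes 7 rose and 0 fell (10 and 0 adjusted over the list alone). GCLM of glutathione synthesis rose by 1.66 and the autophagy receptor SQSTM1 by 1.33. For the list, camera gave 9.04e-13 (adjusted p = 0.102 with an estimated correlation). Of 24 immediate early genes 5 rose and 2 fell (8 and 3 adjusted over the list alone). JUN (1.51), KLF10 (1.43) and DUSP1 (1.16) rose. The list, whose shift ended without the second i14G1-10 library, had an adjusted p of 0.00477 (adjusted p = 0.470 with an estimated correlation).

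A list of genes of start codon choice and upstream reading frames had 5 rises and 1 fall among 24 members (9 and 2 adjusted over the list alone, camera 0.00287, adjusted p = 0.171 with an estimated correlation). It shares 5 members with the ATF4 list, and its other 19 members had a median of 0.06 (camera gave 0.246). Smaller shifts above the other genes were found for initiation factors (3 rose and 2 fell of 49, median 0.20, 7 and 3 adjusted over the list alone), the proteasome (1 and 0 of 35, median 0.20, 1 and 0 adjusted over the list alone) and the nuclear genes of oxidative phosphorylation (4 and 0 of 74, median 0.14, 5 and 0 adjusted over the list alone). Replication histones (4 and 1 of 15, median 0.30, 7 and 1 adjusted over the list alone) and mitochondrial ribosomal proteins (2 and 0 of 71, median 0.12, 0 and 0 adjusted over the list alone) were shifted too. Camera's adjusted p was 0.00672, 6.2e-05, 0.000139, 0.000274 and 0.0201 in that order, and adjusted p = 0.470, 0.417, 0.284, 0.417 and 0.284 with an estimated correlation. All 5 shifts ended under quantile normalisation. Initiation factor members included EIF4G2 (0.58), EIF2S2 (0.56), DENR (−0.88) and PABPC1.

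The other 9 lists did not pass with i14G1-10. For the unfolded protein response of the ER, 2 of 37 genes rose and 1 fell (3 and 1 adjusted over the list alone, median 0.03, −0.04 after rescaling to equal totals, adjusted p = 0.33). XBP1 and HERPUD1 (1.23) rose and ERO1A fell by 0.84. Counts of rises and falls were 0 and 0 of 79 cytosolic ribosomal proteins, 0 and 1 of 22 other TOP mRNAs, 0 and 1 of 25 cholesterol genes, 1 and 0 of 25 glycolysis and hypoxia genes, 3 and 1 of 19 p53 targets, 1 and 1 of 36 G1/S genes, 2 and 0 of 32 G2/M genes, and 0 and 0 of 34 secreted and membrane proteins. Adjusted over the list alone they were 0 and 0, 0 and 2, 0 and 2, 1 and 0, 4 and 3, 1 and 1, 5 and 0, and 0 and 0, and camera gave 0.629, 0.997, 0.591, 0.113, 0.237, 0.198, 0.0709 and 0.121. Under quantile normalisation cytosolic ribosomal proteins passed as lower (median −0.10, camera 0.00072), and fry called p53 targets higher (adjusted p = 0.0437). The TOP list's median was −0.02 while its test pointed up. Members that changed included the hypoxia-responsive VEGFA (1.23), INSIG1 of sterol control (−1.07), the p53 targets SESN2 (1.62) and GADD45A (1.17), and the proliferation marker MKI67 (0.84).

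With i14G1-10 the tests gave 0 lists past the threshold with an estimated correlation. At an unadjusted p under 0.05, 1564 genes differed, and 3749 genes (51.9%) had both treated libraries on 1 side of both DMSO libraries. Exchangeable libraries would give 33.3%. The libraries differed in depth and may share shifts across genes, so the share without any effect may be higher, and 51.9% does not show an excess. The split between rises and falls depended on scaling and on single libraries. Rescaling to equal totals gave 149 and 227 (39.6% rises against 58.4%), DESeq2 gave 122 and 49, and edgeR 299 and 303. Rises and falls were 83 and 19 without the first DMSO library, 104 and 22 without the second, and 320 and 391 without the first i14G1-10 library. Leaving out 1 library at a time moved the 373 calls to between 102 and 711, the lowest without the first DMSO library and the highest without the first i14G1-10 library.

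With i14G1-12, 27 of 30 heat shock genes, 16 of 24 immediate early genes and 31 of 40 genes of the ATF4 list rose, and 1, 2 and 2 fell. HSPA6 went from 0.89 ± 0.664 in DMSO, on 5 reads, to 699 ± 200 on 1333 reads (log2 change 8.55, SE 0.401, adjusted p = 1.38e-11). ZFAND2A, a stress-induced proteasome-associated protein, rose from 4.23 ± 1.23 to 430 ± 89, the immediate early transcription factor EGR1 from 3.77 ± 2.36 to 333 ± 23.4, and DNAJB1 from 187 ± 51.5 to 4537 ± 43.2 (log2 change 4.62, SE 0.146, adjusted p = 9.49e-14). The receptor tyrosine phosphatase PTPRF fell from 150 ± 2.29 to 23.8 ± 8.05 (log2 change −2.65, SE 0.219, adjusted p = 3.39e-08) and SRM from 244 ± 1.91 to 47.5 ± 4.65 (−2.34).

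Of 7224 coding sequences, 1319 rose and 1708 fell with i14G1-12 against DMSO, 438 and 758 of them by at least 2-fold. Further large rises were PPP1R15A (5.45), ATF3 (5.28), CYR61, now CCN1 (4.69), the MAP kinase phosphatase DUSP1 (4.66), BAG3 (4.09) and IER2 (3.91). Further falls were ANKRD52 (−2.56), PTPRS (−2.36), NT5DC2 (−2.33), EI24 (−2.32), the lysosomal glucosidase GAA (−2.29), INTS1 of the Integrator complex (−2.22), the neurofilament NEFL (−2.21) and the polarity protein SCRIB (−2.21). EIF1 rose from 850 ± 47 to 1483 ± 1.26 (log2 change 0.80, SE 0.111, adjusted p = 1.85e-05) and EIF5 from 318 ± 12 to 541 ± 20.2 (0.77, adjusted p = 0.000102), while EIF4G1 had −0.25 (adjusted p = 0.0811, 4 alternatives called it lower). ATF4 rose from 174 ± 3.39 to 914 ± 25.6 (log2 change 2.39, adjusted p = 5.1e-08), XBP1 from 92.3 ± 0.302 to 526 ± 22.8 (5.65-fold), and DDIT3 from 5 reads to 42 (3.55, SE 0.645, adjusted p = 0.00028). HSPA5 had 0.01 (adjusted p = 0.953).

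**Figure D1:**
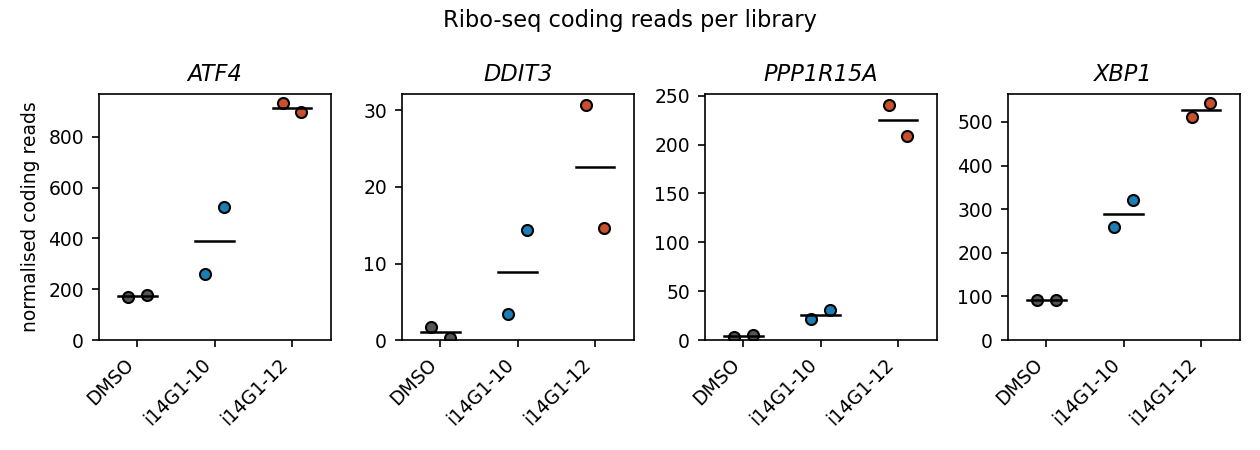
Coding signal (normalised reads, linear axis from 0) of ATF4, DDIT3, PPP1R15A and XBP1 in each of the 6 Ribo-seq libraries (points, lines are means of 2). PPP1R15A had means of 4.23, 26.2 and 225 in DMSO, i14G1-10 and i14G1-12, and DDIT3 rests on 5, 11 and 42 reads.

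Of 30 heat shock genes 27 rose and 1 fell with i14G1-12 (27 and 1 adjusted over the list alone, median 1.13). HSPH1, an Hsp110 chaperone, went from 710 ± 4.18 to 5443 ± 360. Camera gave 6.15e-22 (adjusted p = 0.148 with an estimated correlation). Of 40 genes of the ATF4 list 31 rose and 2 fell (32 and 2 adjusted over the list alone, median 1.06). CHAC1 rose by 3.86 and SLC3A2 by 2.36 (2.9e-20 for the list, adjusted p = 0.148 with an estimated correlation). Of 24 immediate early genes 16 rose and 2 fell (16 and 2 adjusted over the list alone, median 1.64). KLF10 rose by 3.46 and JUN by 3.29 (5.09e-11 for the list, adjusted p = 0.246 with an estimated correlation). NRF2 and oxidative stress genes had 9 rises and 3 falls of 22 (9 and 4 adjusted over the list alone, median 0.19). HMOX1 rose by 2.62 and SLC7A11 by 2.22 (0.00326 for the list, adjusted p = 0.246 with an estimated correlation). The list of start codon choice and upstream frames had 13 rises and 4 falls of 24 (14 and 4 adjusted over the list alone, median 0.55, 8.72e-05, adjusted p = 0.148 with an estimated correlation). IFRD1 rose by 2.80 and ornithine decarboxylase ODC1 fell by 1.71. Its 19 members outside the ATF4 list had a median of 0.40 (unadjusted camera p = 0.0108 at the preset correlation). They were not tested with an estimated correlation.

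Secreted and membrane proteins lay lower with i14G1-12: 1 rose and 17 fell of 34 (1 and 17 adjusted over the list alone, median −0.42), among them the collagens COL4A1 (−2.65) and COL4A2 (−2.16) and NOTCH2 (−1.39). Camera gave 0.000923 (adjusted p = 0.302 with an estimated correlation). The unfolded protein response list was lower as well, with 3 rises and 15 falls of 37 (3 and 15 adjusted over the list alone, median −0.31, 0.0227, adjusted p = 0.342 with an estimated correlation). The ER folding genes DNAJC10 (−1.52) and PDIA4 (−0.88) fell and HERPUD1 (1.52) rose. The shift ended without the second i14G1-12 library. Replication histones had 2 rises and 8 falls of 15 (2 and 8 adjusted over the list alone, median −0.32, 0.0396, adjusted p = 0.583 with an estimated correlation). H1-3 (−1.17) and H1-4 (−0.93) fell, and 5 of the 6 single-library omissions ended the shift.

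Proteasome genes had 15 rises and 0 falls of 35 with i14G1-12 (15 and 0 adjusted over the list alone, median 0.24, 0.000199, adjusted p = 0.414 with an estimated correlation). PSMD12 (0.92) and PSMD7 (0.66) were among the rises. Initiation factors had 23 rises and 4 falls of 49 (23 and 4 adjusted over the list alone, median 0.32, 0.000821, adjusted p = 0.414 with an estimated correlation). EIF2S2 (0.99) and EIF3A (0.87) rose and DENR (−1.24) fell. G1/S genes had 16 rises and 6 falls of 36 (19 and 6 adjusted over the list alone, median 0.32, 0.0159, adjusted p = 0.246 with an estimated correlation). E2F3 (1.14) and CDC6 (0.88) rose and CDK4 (−1.08) fell. Quantile normalisation ended the shifts of initiation factors and G1/S genes. P53 targets had 8 rises and 5 falls of 19 (8 and 5 adjusted over the list alone, median 0.35, 0.0227, adjusted p = 0.246 with an estimated correlation). The pro-apoptotic PMAIP1 rose by 2.40 and CCNG1 fell by 1.21. A minimum mean of 50 ended that shift. SESN2 and GADD45A are also on the ATF4 list, and the other 17 p53 targets had an unadjusted camera p of 0.106.

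The remaining 7 lists did not pass with i14G1-12, with members going both ways. Rises and falls were 4 and 15 of 79 cytosolic ribosomal proteins (3 and 11 adjusted over the list alone, median −0.08), 7 and 6 of 22 other TOP mRNAs (7 and 6), 13 and 10 of 71 mitochondrial ribosomal proteins (13 and 7), 5 and 18 of 74 oxidative phosphorylation genes (5 and 16, median −0.14), 9 and 7 of 25 cholesterol genes (10 and 7), 4 and 6 of 25 glycolysis and hypoxia genes (4 and 6) and 9 and 4 of 32 G2/M genes (10 and 4). Camera gave 0.433, 0.826, 0.281, 0.135, 0.184, 0.826 and 0.0674. Some passed in an alternative. Oxidative phosphorylation genes passed as lower under quantile normalisation (0.000174), on equal totals (0.0338), at a mean of at least 50 (0.0253) and without the second DMSO library (0.0306), and cytosolic ribosomal proteins under quantile normalisation (median −0.15, 0.00396). G2/M genes passed as higher by fry (0.0187) and without the first i14G1-12 library (0.0337). The medians of mitochondrial ribosomal proteins (0.05) and G2/M genes (0.09) turned negative under quantile normalisation and, at −0.05 and near 0, on equal totals. The TOP list's median (−0.09) and its test differed in sign, and the glycolysis list's median (−0.10) and mean (0.01) did. RPL23A (−0.77) and RPS12 (−1.11) fell, MRPL18 (1.83), the cholesterol enzyme HMGCS1 (1.46), the glucose transporter SLC2A1 (1.05) and the spindle protein PRC1 (1.46) rose, and LSS (−1.37) and ATP5G1, now ATP5MC1 (−1.07), fell.

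**Figure D2:**
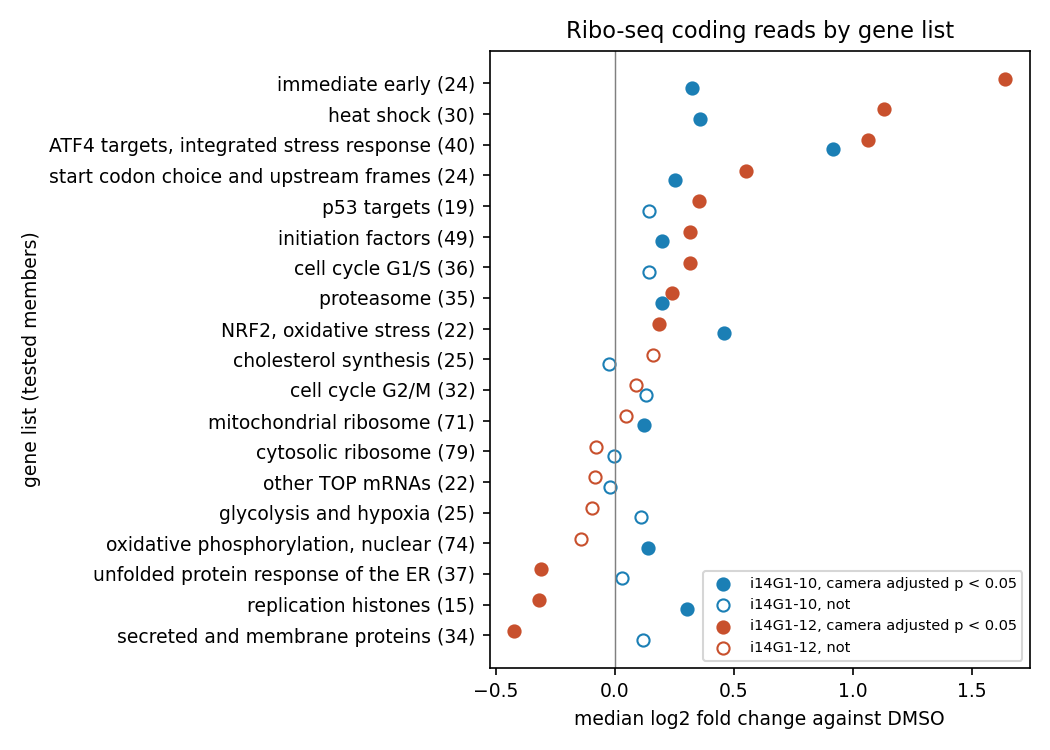
Median log2 change of coding signal for each of the 19 gene lists, with each compound against DMSO (horizontal axis, log2, filled points passed camera at an adjusted p under 0.05). The ATF4 list lies at 0.92 and 1.06 and the immediate early list at 0.32 and 1.64.

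For i14G1-12 no list passed with an estimated correlation; 0 of 19 lists had an adjusted p under 0.05, against 12 by camera with the preset correlation and 10 by fry. At an unadjusted p under 0.05, 3598 genes differed, and 5411 genes (74.9%) had both treated libraries on 1 side of both DMSO libraries. Exchangeable libraries would give 33.3%, and with unequal depth and shifts shared across genes that share may be higher. DESeq2 turned the split to 1270 rises and 971 falls (56.7% against 43.6%), while rescaling to equal totals gave 1106 and 2069 (34.8%) and moved the median of all genes from −0.10 to −0.19. Thinning gave 721 and 1641 (30.5%). The 3027 calls dropped to 1864 (950 rises and 914 falls) and 1939 (919 and 1020) without the first or the second DMSO library, and edgeR gave 1782 rises and 1661 falls.

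The compounds shared many changes, at different doses. Of the genes that rose with i14G1-10, 193 also rose with i14G1-12 (39.8 expected if independent), 122 fell with both (36.6 expected) and 1 was called in opposite directions. Log2 changes against DMSO correlated across genes with r = 0.68 (rho = 0.657) over 7224 genes, where 100 simulations without any effect and with shared controls gave a mean r of 0.308 and at most 0.338. Side by side, with 20 µM i14G1-10 and 10 µM i14G1-12, CHAC1 rose by 3.43 and 3.86, HMOX1 by 2.89 and 2.62, HSPA1B by 2.76 and 3.20, PPP1R15A by 2.37 and 5.45, and HSPA6 by 1.95 and 8.55. Part of the correlation comes from the shared DMSO libraries, which could not be divided between the compounds. The simulations gave all treatments 1 spread per gene. Over genes with at least 20 reads, the variance between the 2 DMSO libraries was 5.07 times counting error. It was 2.03 times with i14G1-10 and 1.33 times with i14G1-12, at lower depth. The r without any effect may therefore lie above the simulated values. The covariance of the changes was 0.227, against at most 0.0186 in the simulations, with the same limit.

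**Figure D3:**
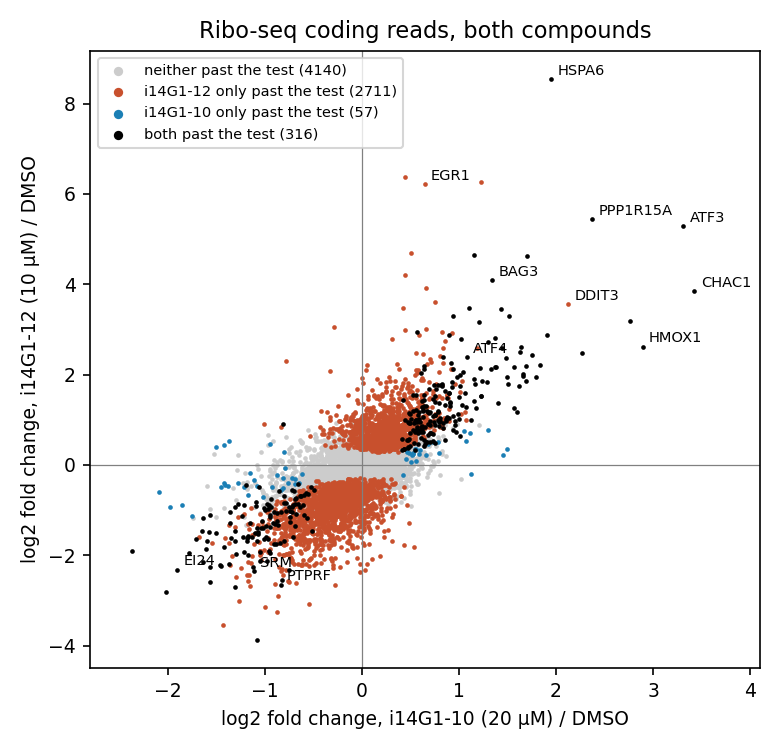
Log2 change of coding signal against DMSO with i14G1-10 (20 µM, horizontal) and i14G1-12 (10 µM, vertical), 1 point per gene. Colours mark the 316 genes called with both compounds, 57 with i14G1-10 alone, 2711 with i14G1-12 alone and 4140 with neither; a call with 1 compound alone is not a test of the difference.

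Compared directly, many heat shock and immediate early genes had more footprints with i14G1-12 than with i14G1-10, and part of the membrane, ER and histone genes had fewer. No list passed with an estimated correlation; 0 of 19 had an adjusted p under 0.05 (smallest 0.191), against 12 by camera with the preset correlation and 10 by fry. HSPA6 was higher by 6.60 (SE 0.401, adjusted p = 1.71e-09), ZFAND2A by 5.93, EGR1 by 5.58, CYR61 by 4.19 and DUSP1 by 3.50. PTPRS (−2.34, SE 0.224, adjusted p = 6.12e-07), the ubiquitin ligase HERC2 (−2.25), CAD of pyrimidine synthesis (−2.01), GAA (−1.99) and INTS1 (−1.92) were lower. ATF4 was higher by 1.31 (SE 0.204, adjusted p = 0.000169), PPP1R15A by 3.07, XBP1 by 0.87, EIF5 by 0.84 and EIF1 by 0.43 (adjusted p = 0.00921, ended without the trend or without either i14G1-12 library). EIF4G1 (−0.22, SE 0.112, adjusted p = 0.153), HSPA5 (−0.25, SE 0.113, adjusted p = 0.112) and DDIT3 (1.43, SE 0.645, adjusted p = 0.111) did not pass, which does not show equal levels. In all, 810 genes were higher and 1014 lower of 7224, 226 and 325 by at least 2-fold.

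Between the compounds, 25 of 30 heat shock genes were higher and 0 lower with i14G1-12 (26 and 1 adjusted over the list alone, median 0.73, camera 1.22e-22, adjusted p = 0.191 with an estimated correlation), as were 18 against 1 of 24 immediate early genes (18 and 2 adjusted over the list alone, median 1.48, 4.58e-17, adjusted p = 0.195 with an estimated correlation). The ATF4 list had 9 higher and 1 lower of 40 (9 and 1 adjusted over the list alone, median 0.20, 0.000129, adjusted p = 0.305 with an estimated correlation). ATF3 was higher by 1.97 and SLC3A2 by 0.87. The list of start codon choice had 11 higher and 2 lower of 24 (11 and 2 adjusted over the list alone, median 0.39, 0.000409, adjusted p = 0.195 with an estimated correlation). AZIN1, which protects ornithine decarboxylase, was higher by 1.75 and ODC1 lower (−1.55). Secreted and membrane proteins had 0 higher and 20 lower of 34 (0 and 22 adjusted over the list alone, 5.72e-08, adjusted p = 0.195 with an estimated correlation). The unfolded protein response had 1 and 16 of 37 (2 and 17 adjusted over the list alone, 0.000339, adjusted p = 0.195 with an estimated correlation). Replication histones had 0 and 11 of 15 (0 and 13 adjusted over the list alone, 2.37e-07, adjusted p = 0.305 with an estimated correlation). Oxidative phosphorylation had 0 and 22 of 74 (0 and 23 adjusted over the list alone, 2.14e-06, adjusted p = 0.195 with an estimated correlation). Examples are NOTCH2 (−1.46), SSR1 of the ER translocon (−0.84), H1-4 (−1.05) and COX7B (−0.89).

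Smaller differences in favour of i14G1-12 passed for initiation factors (10 higher and 3 lower of 49, 10 and 3 adjusted over the list alone, 0.0159, adjusted p = 0.532 with an estimated correlation), cholesterol genes (8 and 2 of 25, 10 and 2 adjusted over the list alone, 0.0278, adjusted p = 0.473 with an estimated correlation), p53 targets (7 and 2 of 19, 8 and 2 adjusted over the list alone, 0.0281, adjusted p = 0.195 with an estimated correlation) and G1/S genes (11 and 3 of 36, 11 and 4 adjusted over the list alone, 0.042, adjusted p = 0.195 with an estimated correlation). Each of these 4 ended in at least 2 alternatives. PABPC1 (0.74), HMGCS1 (1.39), PMAIP1 (1.56) and the licensing factor CDT1 (1.05) were higher. The other 7 lists did not pass: camera gave 0.797 for NRF2 and oxidative stress genes (4 higher and 7 lower), 0.491 for cytosolic ribosomal proteins (1 and 9), 0.608 for other TOP mRNAs (2 and 3), 0.687 for mitochondrial ribosomal proteins (3 and 10), 0.25 for glycolysis and hypoxia genes (3 and 6), 0.0645 for the proteasome (6 and 0, 0.014 without the first i14G1-10 library) and 0.25 for G2/M genes (6 and 4, median and test of opposite sign). Adjusted over the list alone the counts were 6 and 8, 0 and 4, 2 and 3, 3 and 5, 3 and 6, 4 and 0, and 7 and 6. The balance of genes higher and lower depended on the method, with 994 and 674 in edgeR (59.6% higher against 44.4%) and 556 and 290 in DESeq2, and the count dropped to 943 and 849 without the first or the second i14G1-12 library.

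The 5′ UTR column held a larger share of the Ribo-seq reads with both compounds. The 5′ UTR share of Ribo-seq reads was 6.07% ± 0.402 in DMSO, 8.78% ± 1.02 with i14G1-10 and 10.1% ± 0.0834 with i14G1-12 (SD, n = 2 each), a rise of 2.71 and 4.0 percentage points or 1.45-fold and 1.66-fold. Single libraries stood at 5.78% (exact 95% interval 5.76 to 5.81) and 6.35% (6.33 to 6.38) in DMSO, 8.06% (8.01 to 8.10) and 9.50% (9.43 to 9.57) with i14G1-10, and 10.0% (9.95 to 10.1) and 10.1% (10.1 to 10.2) with i14G1-12. All 4 treated libraries were above both DMSO libraries, and the exact two-sided permutation p was 0.333 for each comparison, the smallest that 2 libraries against 2 allow. I14G1-12 was 1.29 points above i14G1-10, a difference that ranged from 0.569 to 2.01 when single libraries were left out. Over 2506 genes with enough reads in both regions, the log2 ratio of 5′ UTR to coding signal was compared with each gene's DMSO mean. The median difference over genes was 0.508 and 0.771 in the i14G1-10 libraries and 0.807 and 0.808 in the i14G1-12 libraries. The DMSO libraries differed from their mean by 0.0725. The ratio was above the DMSO mean for 85.9% and 86.7% of genes with i14G1-10 and for 91.1% and 90.6% with i14G1-12.

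**Figure D4:**
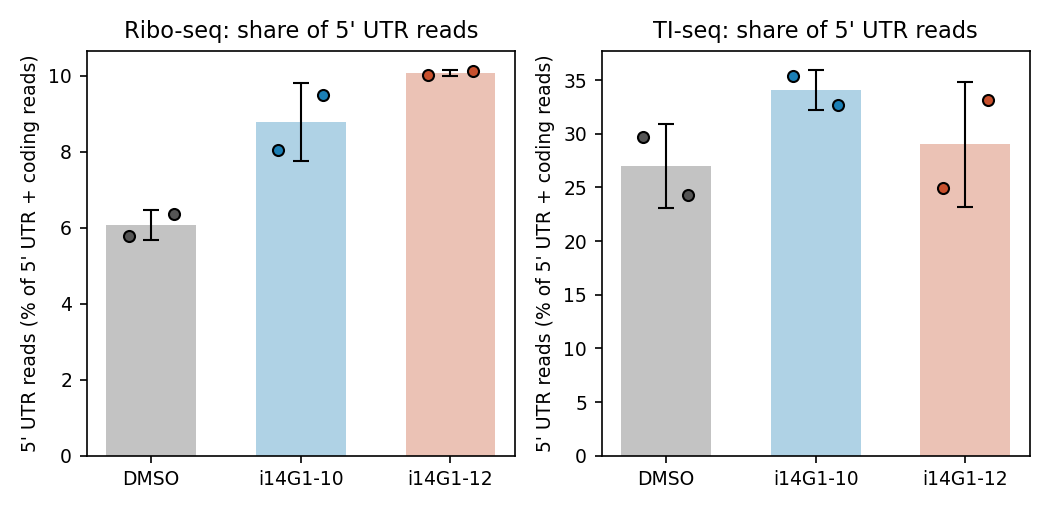
Percentage of 5′ UTR reads among 5′ UTR and coding reads in Ribo-seq (left) and TI-seq (right); points are libraries, bars are means of 2 from 0 and error bars are ± 1 SD. In Ribo-seq the 4 treated libraries lie between 8.06% and 10.1%, above both DMSO libraries.

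Gene by gene, nearly all called changes of the ratio of 5′ UTR to coding signal were rises, and ATF4 and PPP1R15A were among the falls. With i14G1-12 the largest rises were those of RPS12 (2.17, adjusted p = 0.0145), PRRC2C (2.14), histone H1-2 (2.02), BRD2 (1.92), the nucleolar protein NPM1 (1.91), EXO1 (1.90) and PRELID1 (1.76). EIF4G1 (1.01, adjusted p = 0.0233) and EIF5 (0.96, adjusted p = 0.0223) rose, though EIF5 had a ratio change near 0 under quantile normalisation, which takes out the common shift. The 5 falls were MRPL18 (−1.61), ZFAND2A (−1.22), ATF4 (−1.20, adjusted p = 0.017), PPP1R15A (−1.24, adjusted p = 0.0197) and HSPA6, whose DMSO coding signal rested on 5 reads. The ATF4 call ended without either i14G1-12 library. That of PPP1R15A ended there too, without the first DMSO library and after thinning. That of MRPL18 ended without the first i14G1-12 library and after thinning, and that of ZFAND2A in 8 alternatives. With i14G1-10 the rises included H1-2 (2.24, adjusted p = 0.0167), NPM1 (2.20), RHOB (1.78), GAPDH (1.68), BTF3 (1.64) and EIF5 (1.05, adjusted p = 0.0472), while ATF4 (−0.67, adjusted p = 0.175) and PPP1R15A (−0.29, adjusted p = 0.558) did not pass. None of the ratio calls with i14G1-10 remained after thinning, without the trend, under quantile normalisation or at a mean of at least 50.

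The ratio rose for 122 and fell for 0 of 2506 genes with i14G1-10, and rose for 713 and fell for 5 with i14G1-12. At an unadjusted p under 0.05, 749 and 1095 genes differed. For the difference between the compounds limma called 0 genes, with 249 at an unadjusted p under 0.05 and 0 by edgeR. A replicate block gave 8 calls there and fits to only the 4 libraries compared gave 12. With i14G1-10 against DMSO the block gave 387. The number of calls depended on single libraries. With i14G1-10 it was 24 and 246 without the first or second DMSO library, 497 and 0 without the first or second i14G1-10 library, and 17 and 18 without the first or second i14G1-12 library. With i14G1-12 it was 177 without the first DMSO library, and 42 and 68 without the first or second i14G1-12 library. Between the compounds it was 11 and 9 without the first or second DMSO library and 7 without the first i14G1-10 library. Quantile normalisation, which removes a common shift of the ratio by construction, gave 0 calls with i14G1-10 and 9 with i14G1-12 (2 up and 7 down). In the 5′ UTRs themselves, the signal of DDIT3 went from 4.73 ± 0.445 to 53.8 ± 0.667 with i14G1-10 (log2 change 3.26, adjusted p = 5.52e-09) and to 116 ± 19.6 with i14G1-12 (4.34, adjusted p = 1.02e-12). That of ATF3 rose by 3.55 and 5.68, of JUN by 2.01 and 3.83, of EIF1 by 1.19 and 1.58 and of EIF5 by 0.98 and 1.73. ATF4's 5′ UTR had 0.41 with i14G1-10 (adjusted p = 0.242) and rose by 1.19 with i14G1-12 (adjusted p = 0.00054), less than its coding sequence (2.39). The 5′ UTR of ODC1 fell with both compounds (−1.04 and −1.26). With i14G1-10 the 5′ UTR calls of EIF1, EIF5 and ODC1 ended without the second i14G1-10 library, without the trend and after thinning. Leaving out the first DMSO library ended that of EIF1 and leaving out the second that of ODC1. Quantile normalisation, which takes out a shift common to most 5′ UTRs, ended those of EIF1 and EIF5 with i14G1-10 and of EIF1 and ATF4 with i14G1-12, and thinning ended that of EIF1 with i14G1-12.

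In TI-seq, where harringtonine holds ribosomes at start sites, genes of heat shock and of the integrated stress response were again among those that rose with each compound, and huntingtin and the laminin LAMA5 were among those that fell. With i14G1-10, HMOX1 (3.54, SE 0.338, adjusted p = 6.34e-07), CHAC1 (3.20), HSPA1B (3.04), ATF3 (3.02) and SLC7A11 (2.99) rose, as did ATF4 (2.04, adjusted p = 0.000493, ended without the trend or without the second i14G1-10 library). With i14G1-12, EGR1 (6.93), ZFAND2A (5.77), PPP1R15A (5.12), DNAJB1 (5.01), DUSP1 (4.52), ATF3 (4.45), ATF4 (3.23) and EIF5 (1.90, adjusted p = 0.000149) rose. HSPA6 and DDIT3 were at the 1 read minimum in both DMSO libraries. With DMSO set to 3 reads over the group, their coding signal was 5.01-fold and 10.7-fold higher with i14G1-10. With i14G1-12 it was 494-fold and 32.1-fold higher. Huntingtin (HTT) fell with both (−1.90 and −2.66), as did the laminin LAMA5 (−2.45, a call that 4 alternatives ended, and −2.76, ended in DESeq2) and SBF1 (−2.12 and −2.57), and EIF4G1 went from 2388 ± 146 to 1262 ± 48.2 and 1258 ± 41.3 (log2 change −0.92 with each, adjusted p = 0.0282 and 0.0123). Of 76 very long proteins, listed after the data had been seen, 1 rose and 41 fell with i14G1-10 and 1 rose and 39 fell with i14G1-12 (camera p = 2.82e-26 and 4e-16, with an estimated correlation, p = 0.105 and 0.176). The EIF4G1 calls ended in 9 alternatives with i14G1-10 and in 4 with i14G1-12.

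TI-seq coding signal rose for 73 and fell for 410 of 6890 genes with i14G1-10, and rose for 539 and fell for 675 with i14G1-12; 110 genes were higher and 18 lower with i14G1-12 than with i14G1-10. Of genes called higher in Ribo-seq, 36 were also called higher in TI-seq with i14G1-10 (2.25 expected) and 388 with i14G1-12 (101 expected); for falls the shared counts were 15 (8.82 expected) and 403 (159 expected). Heat shock genes had 4 rises and 0 falls of 30 with i14G1-10 (5 and 0 adjusted over the list alone, camera 1.35e-10, adjusted p = 0.377 with an estimated correlation) and 21 and 0 with i14G1-12 (27 and 0 adjusted over the list alone, camera 1.53e-24, adjusted p = 0.167 with an estimated correlation). The ATF4 list had 13 and 0 of 40 (24 and 1 adjusted over the list alone, camera 3.38e-22, adjusted p = 0.231 with an estimated correlation) and 26 and 0 (28 and 2 adjusted over the list alone, camera 2.55e-18, adjusted p = 0.167 with an estimated correlation). COL27A1 (7.36), NKX2-3 (5.64) and POU3F3 (5.01) were also called higher with i14G1-12, on 2 libraries that lay far apart. The balance of rises and falls depended on scaling and on single libraries. On equal totals it was 187 and 127 with i14G1-10 (median of all genes 0.195 against −0.07), 773 and 594 with i14G1-12 (median 0.121) and 80 and 41 between the compounds. Quantile normalisation gave 78 and 68 with i14G1-10 and 93 and 40 between the compounds, and edgeR gave 191 and 461 with i14G1-10. With i14G1-10 the rises and falls were 27 and 33 without the first DMSO library, 23 and 6 without the second, 53 and 214 without the first i14G1-10 library, and 13 and 5 without the second. They were 132 and 641 or 637 without the first or second i14G1-12 library, and 19 and 5 without the variance trend. With i14G1-12 they were 232 and 322 without the first DMSO library, 312 and 209 without the second, 456 and 869 without the first i14G1-12 library, and 498 and 491 without the second. Between the compounds, 136 genes were higher and 115 lower without the first i14G1-12 library, 35 and 2 without the first i14G1-10 library, and 55 and 10 without the second.

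The TI-seq 5′ UTR share was 27.0% ± 3.88 in DMSO, 34.1% ± 1.88 with i14G1-10 and 29.0% ± 5.82 with i14G1-12 (SD, n = 2 each). It was 7.06 points higher with i14G1-10 than with DMSO (exact permutation p = 0.333, the smallest possible; 9.81 and 4.32 without the first or second DMSO library), and 2.05 points higher with i14G1-12 (exact permutation p = 0.667), within the spread between libraries. That second difference was 4.79 without the first and −0.699 without the second DMSO library, and 6.16 without the first and −2.07 without the second i14G1-12 library. Over 4210 genes the TI-seq ratio of 5′ UTR to coding signal had a median log2 change of 0.28 with i14G1-10 and −0.01 with i14G1-12. It rose for 1 gene and fell for 1 with i14G1-10, and for 23 and 13 with i14G1-12. Simulated 4-fold changes of this ratio were recovered in only 3.17%, so few calls do not show an unchanged ratio. The 2 i14G1-12 libraries lay at −0.378 and 0.357 from the DMSO mean.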

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

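The tests on the 4 lists that lay lower with i14G1-12, and those on the genes called lower in TI-seq with each compound, were chosen after the result was seen; the 5′ UTR measures and the list of long proteins were also added after the data had been seen. Of 19 gene lists, 6 had medians of opposite sign with the 2 compounds, and for 5 of these camera found a difference between the compounds. Each is given as the median log2 difference of i14G1-12 from i14G1-10 in Ribo-seq coding signal.

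The unfolded protein response list differed by −0.423 (0.0307 with i14G1-10 and −0.309 with i14G1-12, but −0.0406 and −0.4 on equal totals, where the signs agree; adjusted p = 0.000339; adjusted p = 0.195 with an estimated correlation), and its TI-seq difference was −0.0833 (adjusted p = 0.184). Nuclear oxidative phosphorylation genes differed by −0.269 (0.140 and −0.142; adjusted p = 2.14e-06; adjusted p = 0.195 with an estimated correlation), with −0.242 in TI-seq (adjusted p = 0.000746). Replication histones differed by −0.600 (0.303 and −0.319; adjusted p = 2.37e-07; adjusted p = 0.305 with an estimated correlation), with −0.324 in TI-seq (adjusted p = 0.164). Secreted and membrane proteins differed by −0.456 (0.117 and −0.422; adjusted p = 5.72e-08; adjusted p = 0.195 with an estimated correlation), with −0.355 in TI-seq (adjusted p = 7.32e-06). Cholesterol genes differed by 0.153 (−0.0268 and 0.160, camera adjusted p = 0.0278, adjusted p = 0.473 with an estimated correlation), with 0.325 in TI-seq (adjusted p = 0.0639). The values with an estimated correlation are those of Ribo-seq. In TI-seq 0 lists passed between the compounds with an estimated correlation (smallest adjusted p = 0.067).

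For these 5 lists, the shallow second i14G1-10 library and the deposited scaling were weighed. Without that library 4 of 5 lists kept their direction and an adjusted p under 0.05, and 4 of 5 did under quantile normalisation, and cholesterol genes were the list that was lost (adjusted p = 0.09 and 0.0606). Their mean lay 0.272 above that of the other genes at first (SE over members 0.123), 0.216 without the library (SE 0.122) and 0.214 under quantile normalisation (SE 0.123). The call ended as this excess shrank to under 2 SE, although their median was 0.0983 and 0.201. On equal totals the call stayed, with a median of 0.136 (camera adjusted p = 0.0248). The excess lay near 2 SE in each of the fits above, so for cholesterol genes both explanations stay open. For the 4 lists lower with i14G1-12, the medians without the library were −0.431 (unfolded protein response), −0.334 (oxidative phosphorylation), −0.559 (histones) and −0.459 (secreted and membrane proteins). This argues against that library as the whole cause of their difference. Under quantile normalisation the highest adjusted camera p was 3.87e-05. These lists had been chosen by the same test. Camera compares a list with the other genes, so 1 factor per library largely cancels. That p therefore decides little about the deposited scaling. On equal totals only the unfolded protein response lost its opposite signs. A difference between the compounds, or between 20 and 10 µM, remains a candidate explanation, and the design cannot separate compound from dose.

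The higher 5′ UTR share in Ribo-seq could come from lower depth of the treated libraries, from a few genes, or from start codon footprints counted as 5′ UTR. After thinning every library to the total reads of the shallowest and limiting to 397 genes with a mean of at least 50 normalised reads in both regions, the ratio still rose by a median of 0.677 with i14G1-10 and 0.831 with i14G1-12 (spread of the DMSO libraries 0.222), which argues against the total depth as the cause. Without the 100 genes with most 5′ UTR reads the share rose by 2.16 and 3.15 points (spread 0.477), which argues against a few genes. Across 2506 genes the change of the ratio correlated with the TI-seq excess of the ratio in DMSO at r = 0.196 for i14G1-10 and 0.0108 for i14G1-12; neither value decides, because start codons inside 5′ UTRs are enriched in TI-seq too, so start codon footprints remain open. More initiation inside 5′ UTRs, the biological explanation, may contribute and was not tested apart from it.

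The falls of very long proteins in TI-seq may reflect ribosomes still elongating on long coding sequences in the DMSO TI-seq libraries. There, the TI-seq to Ribo-seq ratio of 76 long proteins lay 2.61 above that of all genes tested in both assays on the log2 scale (SD 0.154 for random lists of the size), as this explanation needs; their TI-seq change (−0.898 and −0.872 from that of all genes) restates the pattern. Less translation of these mRNAs under both compounds is argued against for the 76 as a set, which in Ribo-seq lay 0.0939 (spread 0.0415) and 0.0774 (spread 0.102) above all genes, with 20 higher and 15 lower with i14G1-12. The genes with the largest TI-seq falls are not among the 76. With those added, the 57 genes called lower in TI-seq lay −0.0589 from all genes in Ribo-seq with i14G1-10 (spread 0.0619, TI-seq −1.12), which argues the same way. With i14G1-12, 57 genes were called lower in the same set and lay at −0.584 (spread 0.205, TI-seq −1.4); these were chosen by their TI-seq fall and the changes of both assays correlate (r = 0.641), so this value decides nothing and is no support for less translation. A faster or more complete run-off with the compounds would give lower TI-seq values as well and was not tested.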

How the results depend on the processing

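Pseudocounts, filters, scalings, tests, the replicate block and single-library omissions for Ribo-seq coding signal and lists were chosen before the data were examined; the subtraction of 1 read, the thinning, the edgeR interaction and every alternative for TI-seq counts, ratios and shares were chosen after. With 1 library left in a treatment, limma assumes that it varies like the others. The simulated data had 1 spread per gene over all treatments. There, 66.7% of 2-fold coding changes placed in i14G1-12 were recovered in Ribo-seq and 21.5% in TI-seq. Named results here were the largest rises and falls and the genes always named, not genes named only as list members. Of 1357 values for 72 such coding results in Ribo-seq, 1317 kept direction and call, 28 lost the call, 12 gained a call and 0 turned. Of 1363 in TI-seq, 1278 kept it, 84 lost it, 1 gained a call and 0 turned. Of 996 values for named ratios 831 kept it, 141 lost it, 23 gained one and 1 turned; of 932 for named 5′ UTRs these were 833, 87, 11 and 1. Of 408 values for 34 shifted lists 329 kept their call, 79 lost it and 0 turned; the estimated correlation ended all 34 and fry 11. The ones that turned were the ratio of EIF5 (−0.00189) and the 5′ UTR of EIF4G1 (−0.101) with i14G1-12 under quantile normalisation, which removes a shift common to most genes by construction, and the TI-seq share with i14G1-12, −0.699 without the second DMSO library and −2.07 without the second i14G1-12 library (range on omission −2.07 to 6.16).

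The 373 Ribo-seq calls with i14G1-10 became 121 without trend, 245 with only the 4 libraries compared, 745 with the replicate block (the replicate numbers pair nothing in the labels, and replicate differences correlated between treatments at r = 0.0328 to 0.154 in Ribo-seq coding signal, 0.124 to 0.205 in Ribo-seq 5′ UTRs, −0.146 to 0.173 in TI-seq coding signal and −0.0124 to 0.256 in TI-seq 5′ UTRs), 164 after thinning, 602 in edgeR and 171 in DESeq2. Omitting single libraries gave 102 to 711: 102 and 126 without the first or second DMSO library, 711 and 214 without the first or second i14G1-10 library, and 245 and 236 without the first or second i14G1-12 library. The 3027 calls with i14G1-12 became 1941 at a mean of at least 50, where fewer genes are tested, and 1864 to 3474 on omission (1864 and 1939 without the first or second DMSO library). The 1824 between the compounds became 978 after thinning and 846 in DESeq2, and 849 to 1811 on omission (943 and 849 without the first or second i14G1-12 library).

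For TI-seq, the 483 calls with i14G1-10 became 314 on equal totals, 146 under quantile normalisation, 24 without trend, 794 with only the 4 libraries, 304 with the replicate block and 60 after thinning. Omission gave 18 to 773: 60 and 29 without the first or second DMSO library, 267 and 18 without the first or second i14G1-10 library, and 773 and 769 without the first or second i14G1-12 library. The 1214 with i14G1-12 became 677 after thinning and 521 to 1325 on omission (554 and 521 without the first or second DMSO library). The 128 between the compounds became 44 without trend, 33 after thinning and 37 to 251 on omission (37 and 65 without the first or second i14G1-10 library, 251 without the first i14G1-12 library).

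The 122 ratio calls with i14G1-10 became 0 at a mean of at least 50, 0 under quantile normalisation (which removes the common shift by construction), 0 without trend, 0 after thinning, 17 with only the 4 libraries, 387 with the replicate block and 70 after subtracting 1 read. On omission they ran from 0 to 497: 24 and 246 without the first or second DMSO library, 497 and 0 without the first or second i14G1-10 library, 17 and 18 without the first or second i14G1-12 library. Unadjusted, 749 genes had p under 0.05 in the main limma fit. The 718 with i14G1-12 became 153 at a mean of at least 50, 9 under quantile normalisation, 217 after thinning and 42 to 937 on omission (177 without the first DMSO library, 42 and 68 without the first or second i14G1-12 library). Between the compounds the 0 calls became 2 with a pseudocount of 5, 2 under quantile normalisation, 12 with only the 4 libraries, 8 with the replicate block and 0 to 11 on omission (11 and 9 without the first or second DMSO library, 7 without the first i14G1-10 library), and stayed at 0 in the edgeR interaction.

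Shifted lists numbered 10, 12 and 12 for i14G1-10, i14G1-12 and their difference, and 0 in each with an estimated correlation. With i14G1-10 fry called 5, 4 of them among the 10, and quantile normalisation gave 6, 5 of them among the 10; omission gave 8 to 10, 10 to 12 and 10 to 12. The correlation of both compounds' changes (0.68) was 0.704 at a mean of at least 50, 0.7 under quantile normalisation, 0.661 after subtracting 1 read, 0.658 after thinning and 0.592 to 0.689 on omission. The rise of the 5′ UTR share was 1.99 to 3.43 points with i14G1-10, 3.71 to 4.28 with i14G1-12 (3.15 without the 100 genes with most 5′ UTR reads) and 0.569 to 2.01 between the compounds on omission; the last moves by over 1.5 times without the first or second i14G1-10 library. Apart from the cases explained by construction, the cause was not tested.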

Other observations

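Genes of polyamine supply were among those named by the rule. ODC1 and AZIN1 were named as members of the list of start codon choice and upstream frames, which was set beforehand and tested. No list of polyamine genes had been set and none was tested, and other such genes are not described here. SRM, which makes spermidine, fell by 1.11 with i14G1-10 and by 2.34 with i14G1-12. ODC1, the enzyme before it, fell by 1.71 with i14G1-12 and was lower (−1.55) with i14G1-12 than with i14G1-10. AZIN1, which keeps ODC1 from degradation, was higher by 1.75 with i14G1-12 than with i14G1-10 (adjusted p = 4.78e-07).

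In TI-seq with i14G1-12, 17 of 25 immediate early genes rose and 1 fell (18 and 1 adjusted over the list alone; median 2.47; camera 3.54e-17; adjusted p = 0.0927 with an estimated correlation). P53 targets had 8 rises and 1 fall of 18 there (8 and 1 adjusted over the list alone; median 1.15; 0.00136; adjusted p = 0.27 with an estimated correlation), proteasome genes 10 rises and 1 fall of 35 (13 and 1 adjusted over the list alone; median 0.60; 9.06e-05; adjusted p = 0.299 with an estimated correlation), and secreted and membrane proteins 1 rise and 13 falls of 34 (1 and 14 adjusted over the list alone; median −0.53; 3.27e-05; adjusted p = 0.41 with an estimated correlation). In TI-seq 5′ UTRs, DDIT3 and EGR1 were at the 1 read minimum in both DMSO libraries. With DMSO set to 3 reads over the group, DDIT3 was 50.6-fold higher with i14G1-10 and 53.2-fold higher with i14G1-12. EGR1 was 95.3-fold higher with i14G1-12 on the same terms.

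The ratio of 5′ UTR to coding signal rose less than that of other genes for 4 lists with i14G1-12, so their medians and tests differ in sign: genes of start codon choice (median 0.48, adjusted p = 0.00145), cytosolic ribosomal proteins (0.45, adjusted p = 0.00145), oxidative phosphorylation (0.37, adjusted p = 0.00465) and immediate early genes (0.53, adjusted p = 0.0156). With an estimated correlation their adjusted p lay between 0.51 and 0.53.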
